A study of Oryza sativa with 14 samples.

How the data were processed

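Leaf RNA of rice (Oryza sativa, cultivar Zhonghua 11) was measured by sequencing in 14 libraries from seedlings at the 4-leaf stage. Per the labels' protocols, wild-type (WT) plants and transgenic htg3 mutant lines grew in pots, some pots were kept at 42 °C for 0.5 h and the others stayed at normal conditions, total RNA was taken from leaves with Trizol, and libraries followed standard Illumina protocols. The genotype and treatment labels give 6 groups: untreated WT (WT_control, 3 libraries), untreated cr12 and cr2 (cr12_control and cr2_control, 2 each), heat-treated WT (WT_heat, 3), and heat-treated cr12 and cr2 (cr12_heat and cr2_heat, 2 each). The labels give no batch and no pairing, and replicate numbers follow the order of the samples only. Nothing in the labels says that replicates come from separate plants, so p-values measure the spread between these samples.

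The authors deposited one table of estimated counts per gene for 55986 rice loci named with MSU locus IDs, made with StringTie from read coverage; the values are whole numbers, so rounding altered nothing. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 were used, without stated roles or settings, and the genome build is not given in the sources used here. Totals ran from 92 M to 99.4 M counts per library (M, mega). Low values gather at multiples of 4: 9196 gene-by-library values equal 4 against 3918 equal to 3 and 5346 equal to 5, so 1 sequenced fragment was taken as worth about 4 counts. On that scale the libraries hold 23 M to 24.9 M fragments. The floor for a gene without counts in a group was set at 3 fragments over the group (12 counts), and folds against such a group are given as lower bounds from that floor. Depth gives counting error only. The spread between replicates was larger for well-covered genes, as given with the results.

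Differential expression was computed from the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr over the 6 groups), with 1 fit of the 6 group means to all 14 libraries, so that groups of 2 libraries borrow their spread from all groups. The filter left 28823 tested genes, which hold 99.99% of the counts; 20235 genes had no count in any library. Calls are at a Benjamini-Hochberg adjusted p under 0.05. The 11 comparisons are the heat response in WT, the heat response in the htg3 lines (each line weighted equally), htg3 against WT without and with heat, the difference of both heat responses (the interaction), each line against WT in each treatment, and cr12 against cr2 in each treatment. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over libraries. Log2 changes are given ± an approximate SE, the absolute log2 change divided by the square root of the F statistic. Unless another tool is named, adjusted p-values of genes are from edgeR and those of gene lists from limma 3.58.1.

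Gene lists were tested with camera of limma (preset correlation of 0.01, log2 CPM from voom, adjusted over the 17 lists within a comparison), beside camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. The lists are the heat shock factor (HSF) family, small heat shock proteins, the HSP70, HSP90 and HSP100 families, other heat-inducible regulators, JAZ (TIFY) repressors, jasmonate synthesis and signalling, folding in the endoplasmic reticulum (ER), the photosynthetic apparatus, the circadian clock, cold and drought stress, shoot meristem, dividing cells, root, antioxidant enzymes, and light harvesting and photosystems. A further list, leaf senescence, has 2 members and was too small to test. The lists hold 173 genes, of which 172 are in the table and 167 were tested. The JAZ list follows a published link of HTG3 to JAZ genes and may have been chosen by the study on these samples, so its counts are not independent evidence.

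Comparisons, tests, lists, the rule for naming genes and the alternatives were fixed before the data were examined, with these exceptions. The name table (assembly ASM3414082v1, 39387 genes) carries no MSU IDs, so lists meant to be filled by product name could not be, and the ID members of 4 lists (dividing cells, root, antioxidant enzymes, light harvesting and photosystems) were written down once that was known and before any gene's values were read. Names therefore come from the lists, not from the table of counts. Of 123 listed genes with a symbol of their own, 100 were found in the name table by symbol or synonym; 99 lie on the chromosome their ID gives, 1 on another, and all 495 pairs on 1 chromosome that could be compared stand in the order of their IDs. The other 50 listed genes carry family names. Near-identical copies (clustered small heat shock protein genes on chromosomes 1 and 3, RbcS copies, the HSP90 neighbours LOC_Os09g30412 and LOC_Os09g30418) share reads to an unknown extent, so their single values are uncertain. The locus of HTG3 is not given in the sources used here, so the level of the mutated gene was not checked, and the whole HSF family is reported.

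Genes named are, for each of the 5 main comparisons, those with an adjusted p under 0.05, no overlap of CPM between the arms (for the interaction, the same sign in both lines), a mean of at least 5 CPM in a group compared and a symbol: the 10 largest rises and the 10 largest falls, with the same sign in both lines for htg3 against WT. Every tested HSF and JAZ gene and up to 4 members with the smallest p of each other list may also be named, and up to 2 loci without a symbol per direction are given by ID; any other gene named was chosen after its values were seen. Alternatives were RLE and upper-quartile factors, no filter on low counts, DESeq2 1.42.0, limma voom, a 2-fold minimum, only the groups compared, both lines as 1 group, and each library left out in turn. Counts divided by 4, and a fit without 2 libraries that stand apart (cr2_control replicate 2 and WT_heat replicate 2), were chosen after seeing the data, as was the testing of gene lists with each library left out. Where a library was left out of a group of 2, the lone library is assumed to vary like the other groups.

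The pipeline was tested on simulated counts with known changes. For changes of 2-fold and of 4-fold, it recovered 39.6% and 78.6% in the heat response in WT, 52.5% and 68.7% in the htg3 lines, 50% and 78.6% for htg3 against WT without heat, 57.1% and 73.7% with heat, and 19.6% and 64.6% in the interaction; 2.4 to 6.6% of calls were false over the 11 comparisons, and no simulated change was called with the wrong sign. Few genes changed in each simulation. For the heat response in WT, 96 changed 2-fold and 98 changed 4-fold among 28060 tested. The real heat responses called far more genes, 14722 in WT and 16163 in the htg3 lines. The recovered shares may therefore not hold for the heat responses. Overlaps between comparisons that share WT libraries were set beside 5 simulations without any effect. Figures were drawn with matplotlib 3.10.9.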

Results

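The series searched for genes that depend on HTG3 in rice leaves, without heat and after 0.5 h at 42 °C. The 14 libraries hold 92 M to 99.4 M counts each. Replicates correlated at 0.993 to 0.996 on log counts. Over genes above a minimum count their spread was 11.4 to 39.2 times what sampling alone gives (chi-square per degree of freedom). The first principal component (52.7% of variance) parts heat-treated from untreated libraries. The next components (9.7% and 7.6%) part the htg3 lines from WT and from each other. Within groups, cr2_control replicate 2 lies at -97.6 on PC2 against -57.9 for replicate 1. WT_heat replicate 2 lies at 89.2 on PC4 (4.1% of variance), where the other libraries span -32.3 to 45.

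**Figure D1:**
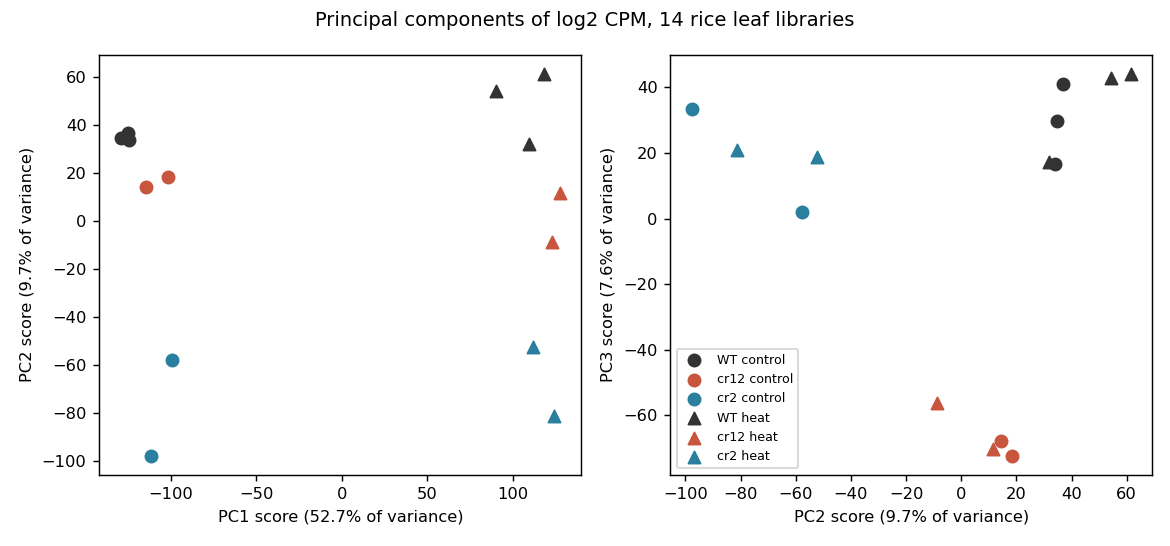
First against second principal component of log2 CPM (52.7% and 9.7% of variance, scores without unit), 1 point per library, with colour for genotype and shape for treatment. Heat-treated libraries lie at 90.6 to 127.5 on the first component and untreated ones at -129.1 to -99.1.

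Heat raised most chaperone genes in WT leaves, some of them by orders of magnitude and others by little. Small heat shock proteins, which hold unfolding proteins soluble, rose in all 17 tested members. LOC_Os01g04380 went from 1.13 ± 0.118 to 901 ± 129 CPM (n = 3 each, log2 change 9.63 ± 0.26, adjusted p = 3.1e-10) and LOC_Os03g16020 from 1.18 ± 0.352 to 6140 ± 825 CPM. LOC_Os03g14180 had no count in untreated WT and 965 ± 156 CPM after heat, at least 24100-fold higher, while LOC_Os01g04350 rose from 195 ± 8.24 to 306 ± 28 CPM (0.65 ± 0.13). Of the HSP70 chaperones 7 of 8 rose, among them LOC_Os01g62290, from 68.9 ± 7.82 to 11300 ± 989 CPM (7.36 ± 0.36, adjusted p = 1.4e-08). The HSP70 gene LOC_Os03g60620 rose by 0.48 ± 0.10 and LOC_Os11g47760 by 1.03 ± 0.14, and LOC_Os12g14070, at 138 ± 14.5 and 140 ± 9.22 CPM, gave no call (adjusted p = 0.86). Of the HSP90 family 5 of 6 were called higher by edgeR and 6 by voom, among them LOC_Os06g50300, from 190 ± 6.7 to 3540 ± 134 CPM (4.22 ± 0.10, adjusted p = 2.5e-10), and LOC_Os09g30412 by 2.88 ± 0.12. All 6 stood higher in every heat-treated WT library than in any untreated WT library. HSP101, which pulls proteins out of aggregates, rose from 1.49 ± 1.01 to 4440 ± 508 CPM, and all 4 members of the HSP100 family rose. Of the other heat-inducible genes 7 of 8 rose, among them the galactinol synthase gene GolS1 (51.8 ± 6.09 to 630 ± 134 CPM, 3.60 ± 0.16) and the peroxidase gene APX2 (3.43 ± 0.19).

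As lists these families stood above the other genes. The adjusted p was 5.6e-12 for small heat shock proteins (adjusted p = 0.1 with an estimated correlation). It was 2.4e-06 for HSP70 (0.035 with an estimated correlation), 6.5e-06 for HSP90 (0.035), 7.9e-05 for HSP100 (0.067) and 4.2e-05 for other heat-inducible genes (0.045). The median log2 change of the small heat shock proteins was 10.92, or 9.73 with the 3 members without untreated counts at their bounds.

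Heat shock factors, the regulators of these chaperones, split in WT, with 16 of 25 rising and 3 falling. HSFA2a rose from 0.15 ± 0.144 to 1290 ± 77.5 CPM and HSFA2c from 17.2 ± 0.614 to 1370 ± 133 CPM (6.32 ± 0.16, adjusted p = 2.5e-10). HSFA2f rose from 0.029 ± 0.0503 to 288 ± 47.7 CPM and HSFB2c from 16.7 ± 3.87 to 638 ± 26.5 CPM. HSFA2b, HSFA2d, HSFA2e, HSFA3, HSFA4b, HSFA4d, LOC_Os03g12370, HSFB1, HSFB2a, HSFB2b, HSFB4c and HSFC2b rose by 1.04 to 6.87. HSFA1 fell from 87.3 ± 3.41 to 52 ± 1.57 CPM (-0.75 ± 0.07, adjusted p = 1.7e-06), and HSFC1a (-2.22 ± 0.38) and HSFC2a (-0.82 ± 0.17) fell too. HSFA5, LOC_Os01g39020, HSFB4a, HSFB4b, HSFB4d and HSFC1b gave no call. The list had an adjusted p of 3.9e-06 (adjusted p = 0.035 with an estimated correlation) and a median of 2.12, or 1.48 with HSFB4a at its bound. Folding enzymes of the ER rose in all 5 members (7.6e-07, adjusted p = 0.045 with an estimated correlation), led by the disulfide isomerase PDIL2-3 (4.70 ± 0.12) and the chaperone BiP1 (142 ± 19.9 to 3600 ± 51.2 CPM, 4.66 ± 0.15).

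JAZ genes, which code for repressors of jasmonate responses, rose in 11 of 13 members in WT. This list may have been chosen by the study on these samples, so the count is not independent evidence. JAZ6 rose from 37.6 ± 1.92 to 428 ± 91.2 CPM (3.51 ± 0.21, adjusted p = 7e-08), JAZ12 from 4.47 ± 0.394 to 85.9 ± 33.6 CPM (4.26 ± 0.29) and JAZ13 by 5.32 ± 0.64. JAZ3 (-0.23 ± 0.15, adjusted p = 0.22) and JAZ4 gave no call. JAZ2, at least 2.84-fold higher at 0.113 CPM, lost its call with voom (0.085) and with counts divided by 4 (0.079), and ranged from 0.00087 to 0.085 over 7 alternatives. The list had an adjusted p of 3.2e-05 (adjusted p = 0.21 with an estimated correlation) and a median of 3.82, or 3.66 with JAZ2 at its bound. Jasmonate synthesis and signalling went both ways (list adjusted p = 0.3). AOS1 (1.53 ± 0.14), AOC (1.75 ± 0.15), OPR7, JAR1 and MYC2 (1.3 ± 0.15) rose, and AOS2 (-1.45 ± 0.25), COI1a and COI1b fell.

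Photosynthesis genes fell in heat-treated WT. RCA, the activase of Rubisco, went from 16000 ± 1240 to 1650 ± 539 CPM (-3.27 ± 0.24, adjusted p = 4.1e-07). The photosynthetic apparatus fell in 5 of 7 genes (list 0.012, adjusted p = 0.44 with an estimated correlation) and light harvesting in 6 of 13 (0.023, adjusted p = 0.61 with an estimated correlation). The light harvesting list was not called without WT_control replicate 2 (median -0.42, 0.059) or WT_heat replicate 3 (-0.33, 0.065). Clock genes moved in all 9 members, 5 up and 4 down (list 0.99). Whether heat-treated and untreated leaves differed in their time of harvest was not tested. LHY, a morning regulator, went from 2940 ± 148 to 89.4 ± 6.08 CPM (-5.04 ± 0.13, adjusted p = 2.5e-10), and PCL1 rose by 4.48 ± 0.37. Of the cold and drought genes 5 of 9 rose and 2 fell (0.042, adjusted p = 0.32 with an estimated correlation), with DREB1C up from 0.212 ± 0.0914 to 16.6 ± 5.4 CPM and DREB1A changed by -3.73 ± 0.58. That list was not called without WT_control replicate 1 (0.051) or 3 (0.062) or WT_heat replicate 3 (0.05). The senescence regulator NAP fell from 34.5 ± 11.3 to 10 ± 1.11 CPM, and SGR gave no call (-0.24 ± 0.21, adjusted p = 0.35).

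Dividing-cell markers rose in 7 of 12 genes in WT (list 0.052), among them MCM7, a subunit of the replication helicase, from 1.34 ± 0.15 to 6.6 ± 0.771 CPM (2.30 ± 0.30, adjusted p = 4e-05). The CYCB2;2 call was lost without WT_heat replicate 3 (1.42, 0.056), and the CDKB2;1 call with voom (0.089, against 0.00016 to 0.089 over 8 alternatives). Antioxidant enzymes (5 up and 1 down of 8, list 0.072) and root markers (1 up and 1 down of 7, list 0.94) gave no list call. Of the shoot meristem markers 0 of 3 were called by edgeR (list 0.99), with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and voom. In all, 7134 genes rose and 7588 fell, 14722 of 28823 tested, 7527 of them at least 2-fold. Counts adjusted over the list alone equal the list counts throughout. Among loci without a symbol, LOC_Os02g15930 rose from 0.808 ± 0.336 to 1740 ± 118 CPM and LOC_Os08g08850 fell from 35.4 ± 7.13 to 0.0792 ± 0.102 CPM.

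**Figure D2:**
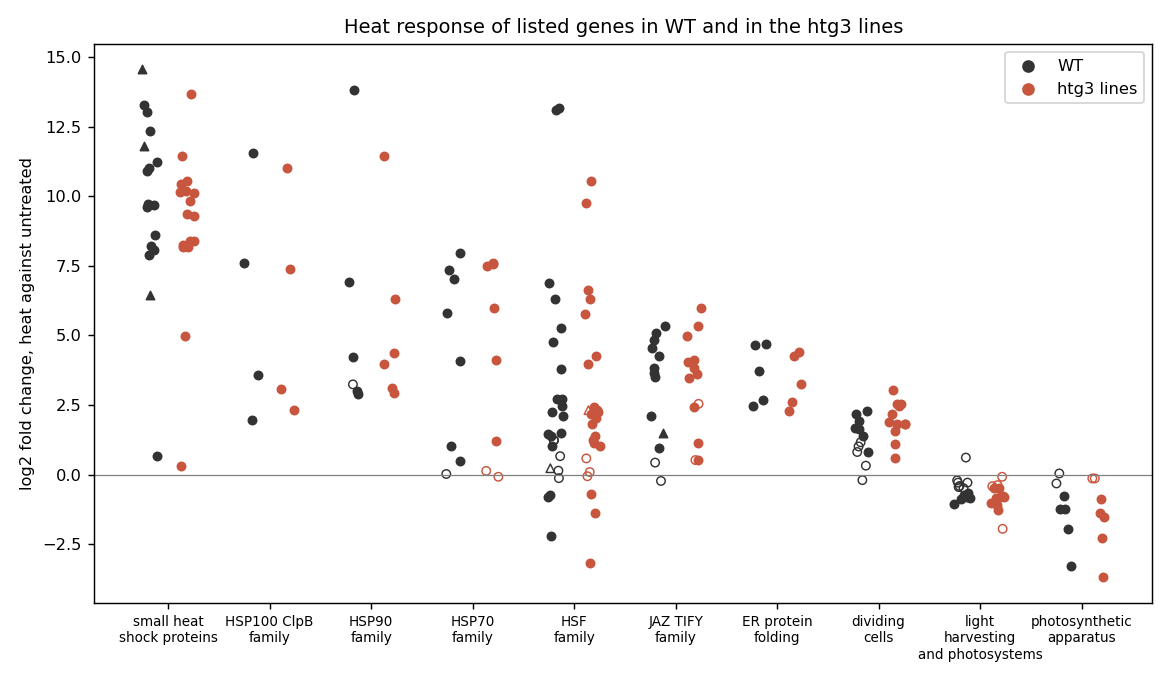
Fitted log2 change with heat of each tested member of the gene lists shown, by list, in WT (black) and the htg3 lines (red). Filled points were called at an adjusted p under 0.05 and open points were not. Triangles mark genes without untreated counts, drawn at their lower bound. All 17 small heat shock proteins have log2 changes above 0 in both genotypes (medians of the fitted values, without the bounds, 10.92 and 9.35).

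In the htg3 lines the same treatment raised all 17 small heat shock proteins as well. LOC_Os01g04380 reached 511 ± 77.5 CPM in cr12 and 518 ± 117 CPM in cr2 (n = 2 each, 8.25 ± 0.21, adjusted p = 8.2e-11), and the list had an adjusted p of 8.7e-11 (adjusted p = 0.06 with an estimated correlation) and a median of 9.35, or 10.04 without cr12_control replicate 2. HSP90 rose in 6 of 6 members (1.2e-05, adjusted p = 0.045 with an estimated correlation) and HSP70 in 6 of 8 (2.5e-05, adjusted p = 0.054 with an estimated correlation). In replicate 2 of cr12_control and of cr2_control the HSP90 gene LOC_Os09g30418 had 0 CPM, against 125.7 and 121.33 in replicate 1. The HSP90 gene LOC_Os08g39140 stood there at 237.49 and 144.79 CPM, against 48.86 and 55.96, and at 214.52 in WT_control replicate 1. After heat it stood at 2246.52 CPM in cr2_heat replicate 2, against 10356.27 in replicate 1. The cause was not tested, so the size of both rises is uncertain. HSP100 rose in 4 of 4 (0.00014, then 0.06), other heat-inducible genes in 7 of 8 (6.5e-05, then 0.054) and ER folding in 5 of 5 (4.5e-06, then 0.054), where the later adjusted p has an estimated correlation. Adjusted over the list alone these counts were the same. Of the heat shock factors 18 of 25 rose and 3 fell (19 and 3 adjusted over the list alone), with a list adjusted p of 8.5e-06 (adjusted p = 0.046 with an estimated correlation) and a median of 2.16. HSFA2c rose by 6.31 ± 0.14 (adjusted p = 6.9e-11). HSFB4b (2.30 ± 0.52, adjusted p = 0.0023) and HSFC1b (2.16 ± 0.63, adjusted p = 0.011) were called here. HSFC1b lost its call without cr2_heat replicate 2 (1.59, 0.06) and ranged from 0.0012 to 0.051 over 9 alternatives.

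JAZ genes rose in 11 of 13 in the htg3 lines (12 adjusted over the list alone), which again is not independent evidence. JAZ3 rose by 0.52 ± 0.13 (adjusted p = 0.0046), and JAZ2 and JAZ4 gave no call. The list had an adjusted p of 4.5e-06 (adjusted p = 0.15 with an estimated correlation). Jasmonate synthesis went both ways, 6 up and 3 down of 11 (6 and 4 adjusted over the list alone, list 0.12), with AOS1 at 2.11 ± 0.12 and MYC2 at 1.96 ± 0.13. All 12 dividing-cell markers rose (0.00013, adjusted p = 0.31 with an estimated correlation, median 1.86). The photosynthetic apparatus fell in 5 of 7 genes (0.0051, adjusted p = 0.39 with an estimated correlation) and light harvesting in 9 of 13 (0.0036, adjusted p = 0.43 with an estimated correlation). RCA went from 17200 ± 259 to 1010 ± 283 CPM in cr12 and from 17200 ± 1650 to 1760 ± 156 CPM in cr2 (-3.69 ± 0.21, adjusted p = 3.5e-08), and NAP fell by a log2 change of -1.88 ± 0.25.

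Clock genes (4 up and 4 down of 9, list 0.83), cold and drought genes (6 and 2 of 9, 0.12), root markers (1 and 1 of 7, 0.93) and antioxidant enzymes (4 and 2 of 8, 5 and 2 adjusted over the list alone, 0.12) gave no list call in the htg3 lines. Of the shoot meristem markers 0 of 3 were called by edgeR (list 0.93), with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and voom. In all, 7954 genes rose and 8209 fell, 16163 together, 7941 of them at least 2-fold. The WT and htg3 responses share no library. They had 12552 called genes in common, 41 of them in opposite directions, and 6143 shared rises where independent lists give 1970. Across genes, which are not independent replicates, r was 0.752. A call in a single genotype does not show that the responses differ, which the interaction tests.

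Without heat, few listed genes differed between the htg3 lines and WT. The disulfide isomerase PDIL1-1 stood at 104 ± 6.6 CPM in cr12 and 108 ± 0.234 CPM in cr2 (n = 2 each) against 84 ± 1.86 CPM in WT (n = 3, 0.34 ± 0.07, adjusted p = 0.02). It was the only call among 167 listed genes with edgeR (36 at an unadjusted p under 0.05, DESeq2 20, voom 4). The call was lost without WT_control replicate 1 (0.35, 0.064), 2 (0.33, 0.082) or 3 (0.33, 0.079), cr12_control replicate 1 (0.31, 0.056) or cr2_control replicate 2 (0.34, 0.058). Its adjusted p ranged from 5.8e-08 to 0.15 over 9 alternatives. Among loci without a symbol, LOC_Os03g02470 stood at 0.0742 ± 0.129 CPM in WT against 61.9 ± 0.62 in cr12 and 44.5 ± 5.28 in cr2 (9.40 ± 0.58, adjusted p = 1.1e-05). LOC_Os12g05290 stood at 0.304 ± 0.0296 against 19.7 ± 0.715 and 10.5 ± 3.29 CPM. LOC_Os04g42120 was lower in the htg3 lines, at 0.414 ± 0.0281 and 0.442 ± 0.0295 CPM against 5.3 ± 0.42 in WT (-3.63 ± 0.34, adjusted p = 0.00022).

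Of the heat shock factors 0 of 25 were called by edgeR without heat (4 at an unadjusted p under 0.05, DESeq2 1, voom 0). Their list had an adjusted p of 0.83 with a test toward lower, a median of -0.03 and a mean of 0.24. Of the small heat shock proteins edgeR called 0 of 17 (5 at an unadjusted p under 0.05, DESeq2 4, voom 0, and 3 up and 2 down adjusted over the list alone). Several heat-induced genes stood higher in cr12_control replicate 2 than in replicate 1, with LOC_Os03g16020 at 16.7 against 1.04 CPM, LOC_Os01g08860 at 17.9 against 3.06, HSP101 at 8.73 against 1.37 and HSFA2a at 6.69 against 0. Others went the other way, such as HSFA2d at 32 against 137 CPM and the HSP70 gene LOC_Os11g47760 at 727 against 806. The median of the small heat shock proteins, 0.62, was -0.14 without replicate 2 (0 called) and 0.98 without replicate 1 (4 called, list 0.019). In cr12 alone against WT it went from 0.78 to -0.34 without replicate 2. Of the JAZ genes edgeR called 0 of 13 (4 at an unadjusted p under 0.05, DESeq2 3, voom 0, and 4 adjusted over the list alone, not independent evidence). HSP70 genes had 0 calls of 8 with edgeR (4 at an unadjusted p under 0.05, DESeq2 2, voom 1, and 2 lower adjusted over the list alone). ER folding stood higher as a list (0.003, adjusted p = 0.84 with an estimated correlation), with 1 of 5 called, 3 adjusted over the list alone, and a median of 0.34. Dividing-cell markers stood higher too (0.013, adjusted p = 1 with an estimated correlation, median 0.73), with 0 of 12 called by edgeR (6 at an unadjusted p under 0.05, DESeq2 2, voom 0), and the list was not called without WT_control replicate 2 (0.75, 0.067). Every other list had an adjusted p of 0.83 or more. In all, 502 genes were higher and 383 lower, 885 together, 386 of them at least 2-fold. The count was 331 without WT_control replicate 1, 467 without WT_control replicate 2, 516 without WT_control replicate 3, 431 without cr12_control replicate 2 and 487 without cr2_control replicate 2.

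After heat, single genes of jasmonate synthesis, JAZ repressors and chaperones differed between the htg3 lines and WT. AOS1, an enzyme of jasmonate synthesis, stood at 94.1 ± 9.79 CPM in cr12 and 81.1 ± 2.64 CPM in cr2 (n = 2 each) against 50.7 ± 10.7 CPM in WT (n = 3, 0.78 ± 0.13, adjusted p = 0.0069). The repressor gene JAZ3 stood at 105 ± 20.9 and 90.3 ± 26.6 against 58.2 ± 6.28 CPM (0.74 ± 0.14, adjusted p = 0.013). JAZ3 had 0.064 in a fit of only the groups compared and 0.061 without the 2 libraries that stand apart, and ranged from 9.1e-05 to 0.064 over 9 alternatives. The HSP70 gene LOC_Os03g16920 was lower, at 393 ± 29.9 and 477 ± 111 against 827 ± 150 CPM (-0.93 ± 0.14, adjusted p = 0.0053). The small heat shock protein gene LOC_Os01g04380 was lower as well, at 511 ± 77.5 and 518 ± 117 against 901 ± 129 CPM (-0.81 ± 0.16, adjusted p = 0.016). GolS1 was lower (-0.63 ± 0.14, adjusted p = 0.021), but not called without WT_heat replicate 2 (-0.49, 0.063) or cr2_heat replicate 2 (-0.67, 0.058). The clock gene PRR95 was lower (-0.39 ± 0.09, adjusted p = 0.023), but not called without WT_heat replicate 1 (-0.38, 0.065) or cr2_heat replicate 2 (-0.41, 0.056). Over 9 alternatives GolS1 ranged from 0.00024 to 0.066 and PRR95 from 3.4e-05 to 0.22.

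**Figure D3:**
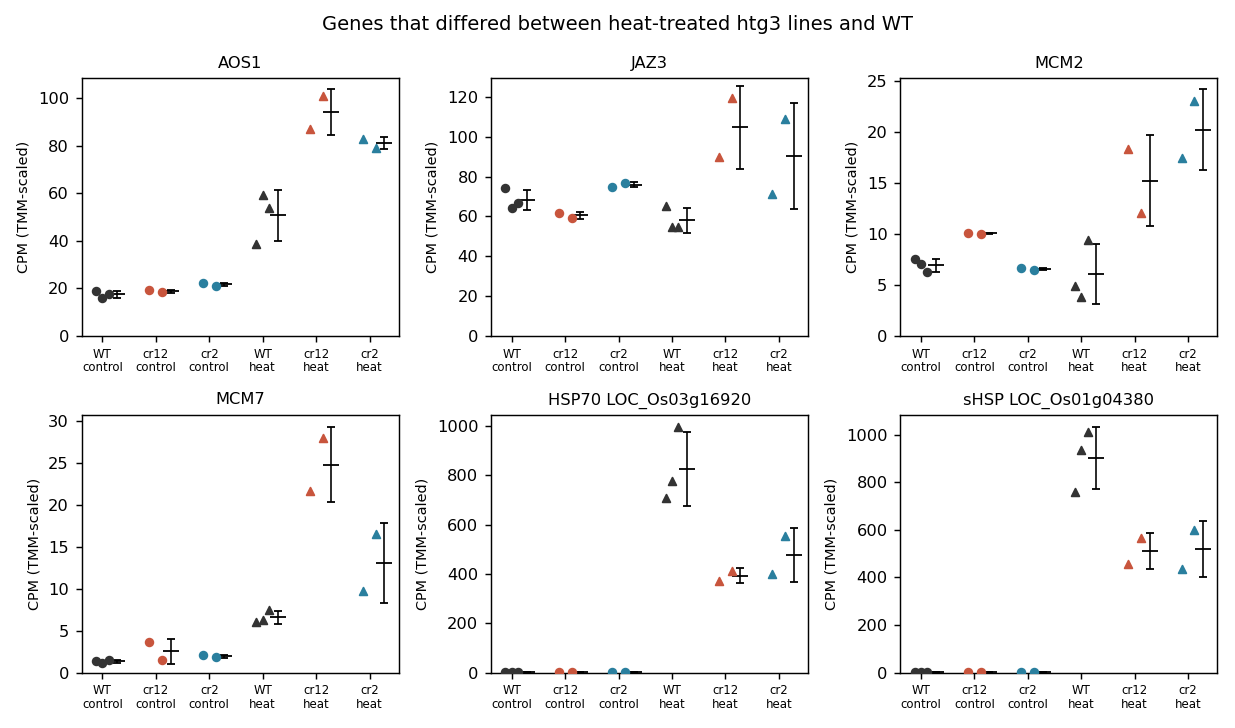
Expression (CPM on TMM-scaled library sizes) of 6 genes that differed between heat-treated htg3 lines and WT, with points for libraries (circles untreated, triangles heat-treated) and a bar of mean ± SD beside each group. After heat AOS1, JAZ3, MCM2 and MCM7 lie higher in cr12 and cr2 than in WT, and the HSP70 gene LOC_Os03g16920 and the small heat shock protein gene LOC_Os01g04380 lie lower (827 and 901 CPM in WT).

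Subunits of the MCM helicase, which opens DNA for replication, were higher in the heat-treated htg3 lines. MCM2 stood at 15.2 ± 4.45 in cr12 and 20.2 ± 3.95 in cr2 against 6.03 ± 2.95 CPM in WT (1.54 ± 0.27, adjusted p = 0.0095), with 0.053 in a fit of only the groups compared and 6.8e-07 to 0.053 over 9 alternatives. MCM7 stood at 24.8 ± 4.5 and 13.1 ± 4.78 against 6.6 ± 0.771 CPM (1.45 ± 0.27, adjusted p = 0.011), but was not called without WT_heat replicate 1 (1.37, 0.052). MCM3 (1.85 ± 0.40, adjusted p = 0.021) lost its call without WT_heat replicate 1 (1.53, 0.069), WT_heat replicate 2 (1.74, 0.069), cr12_heat replicate 1 (1.54, 0.053) or cr2_heat replicate 2 (1.56, 0.07). The cyclin gene CYCB1;1 (1.69 ± 0.43, adjusted p = 0.036) lost its call without WT_heat replicate 1 (1.31, 0.089), WT_heat replicate 2 (1.52, 0.11), cr12_heat replicate 1 (1.5, 0.084) or cr2_heat replicate 2 (1.56, 0.1). MCM4 (adjusted p = 0.041, lost in 12 of 23 settings), HSFC2b (0.05), LOC_Os01g04350 (0.048) and DREB2B (0.048, each lost in 16 of 23) and PT2 (0.038, lost in 17 of 23) are not relied on. As a list, dividing-cell markers stood higher (8.4e-11, adjusted p = 0.3 with an estimated correlation, median 1.61). Of these 5 of 12 were called, 12 adjusted over the list alone, 12 by DESeq2 and 10 by voom.

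JAZ genes stood higher as a list after heat (0.00031, adjusted p = 0.48 with an estimated correlation), with a median of 0.62. Of these 12 of 13 were positive and 1 was called, also adjusted over the list alone, which is not independent evidence. Small heat shock proteins stood lower (0.00026, adjusted p = 0.48 with an estimated correlation, median -0.35), with 2 of 17 called and 2 adjusted over the list alone. Each line was also set against WT: in cr2 all 17 were negative (1.8e-05, adjusted p = 0.43 with an estimated correlation, median -0.45), while in cr12 6 of 17 were positive (0.028, adjusted p = 0.62 with an estimated correlation, median -0.19). The cr12 list was not called without WT_heat replicate 2 (-0.14, 0.14) or 3 (-0.12, 0.063), cr12_heat replicate 1 (-0.11, 0.22) or cr12_control replicate 1 or 2 (-0.17, 0.08 each). LOC_Os03g16020 stood at 7940 CPM in cr12 against 6140 in WT. Compared directly after heat, cr12 against cr2 gave no list call for small heat shock proteins (0.097, median 0.18). There edgeR called 0 of 17 (3 at an unadjusted p under 0.05, DESeq2 2, voom 0), so a difference between the lines was not shown. Clock genes stood lower (0.0076, adjusted p = 0.2 with an estimated correlation, median -0.23), with 1 of 9 called and 3 adjusted over the list alone. Jasmonate synthesis (0.064, 1 of 11 called, 2 adjusted over the list alone), HSP70 (0.14, 1 of 8), other heat-inducible genes (0.19, 2 of 8) and the heat shock factors (0.23, 1 of 25, 0 adjusted over the list alone) gave no list call. ER folding had a median of 0.02, or -0.01 under RLE scaling (list 0.7), and the remaining lists had adjusted p-values of 0.21 to 0.9.

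Altogether 999 genes were higher and 1078 lower in the heat-treated htg3 lines, 2077 together, 635 of them at least 2-fold. The count was 718 without WT_heat replicate 1, 1125 without WT_heat replicate 2, 1331 without cr12_heat replicate 1, 1160 without cr12_heat replicate 2 and 732 without cr2_heat replicate 2. LOC_Os03g02470 again stood at 0.22 ± 0.0264 CPM in WT against 58.4 ± 7.58 and 40 ± 1.07. LOC_Os11g22350 stood at 12.3 ± 2.23 CPM in WT against 0.561 ± 0.378 and 0.597 ± 0.257. Without and with heat, htg3 against WT shared 276 higher and 77 lower genes, where independent lists give 17.4 and 14.3, with no library in common.

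The interaction asks which genes responded to heat differently in the htg3 lines than in WT. LOC_Os12g07970 rose from 3.95 ± 0.503 to 15.4 ± 0.561 CPM in WT (n = 3). In cr12 it went from 6.07 ± 1.54 to 5.35 ± 0.454 and in cr2 from 4.83 ± 0.375 to 4.65 ± 1.75 CPM (n = 2 each, difference of log2 responses -2.08 ± 0.26, adjusted p = 0.03). LOC_Os09g28210 rose from 2.61 ± 0.0914 to 40.1 ± 10.9 CPM in WT and from 0.754 ± 0.231 to 53.4 ± 10.1 in cr12 (1.85 ± 0.27, adjusted p = 0.042). LOC_Os03g04530 rose from 0.145 ± 0.0605 to 10.3 ± 4.21 CPM in WT (difference -3.53 ± 0.46, adjusted p = 0.03). It went from 2 ± 0.717 to 29.3 ± 0.221 CPM in cr12 and from 11.5 ± 0.666 to 29.5 ± 3.74 CPM in cr2. Its smaller fold in the lines thus goes with a higher untreated level there, and after heat it stood above WT in both lines. LOC_Os04g49757 fell from 23.3 to 1.76 CPM in WT, from 13.6 to 3.19 in cr12 and from 10.7 to 2.96 in cr2 (1.76 ± 0.25, adjusted p = 0.036). Of 167 listed genes 0 were called by edgeR (25 at an unadjusted p under 0.05, DESeq2 7, voom 0). The small heat shock protein gene LOC_Os01g04380 had -1.39 ± 0.25 (adjusted p = 0.058), GolS1 -0.83 ± 0.19 (0.096), AOS1 0.58 ± 0.18 (0.18) and JAZ3 0.75 ± 0.20 (0.13).

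Jasmonate synthesis and signalling changed more positively in the htg3 lines than in WT as a list (0.014, adjusted p = 0.72 with an estimated correlation), with a median of 0.42, 9 of 11 positive and 2 called adjusted over the list alone. This includes smaller falls, as for AOS2 (-1.45 in WT and -0.87 in the htg3 lines). The list was not called without WT_control replicate 3 (0.061), WT_heat replicate 1 (0.065) or 3 (0.057) or cr2_heat replicate 1 (0.092). Dividing-cell markers changed more positively too (0.014, adjusted p = 0.95 with an estimated correlation, median 0.73, 1 adjusted over the list alone), but not without WT_control replicate 3 (0.072) or WT_heat replicate 1 (0.077). ER folding rose less (0.032, adjusted p = 0.72 with an estimated correlation), with a median of -0.31 and 5 of 5 negative. It was not called without WT_control replicate 2 (0.12) or 3 (0.061), cr12_control replicate 1 (0.12), WT_heat replicate 1 (0.065) or 2 (0.093), cr12_heat replicate 1 (0.075) or cr2_heat replicate 2 (0.059). The heat shock factors (0.61), small heat shock proteins (0.15, 2 lower adjusted over the list alone) and clock genes (0.17) gave no list call. The median of the small heat shock proteins, -0.83, was 0.06 without cr12_control replicate 2 and -1.22 without replicate 1 (3 called, list 5.6e-06). JAZ genes gave none either (0.33), with a test toward higher, a median of 0.09 and a mean of -0.17, and 1 called adjusted over the list alone, not independent evidence. The remaining lists had adjusted p-values of 0.61 to 0.99.

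Altogether 33 genes differed in their heat response (3987 at an unadjusted p under 0.05, DESeq2 1247, voom 10). Of these 60.6% responded more positively in the htg3 lines, against 25% of 12 genes under RLE scaling. Without WT_control replicate 1 the count was 1, without WT_control replicate 3 it was 5, and without WT_control replicate 2 edgeR called 0 (3515 at an unadjusted p under 0.05, smallest adjusted p 0.079). It was 13 without cr12_control replicate 2, 3 without cr2_control replicate 1, 2 without cr2_control replicate 2, 5 without WT_heat replicate 1 and 84 without WT_heat replicate 3. It was 15 without cr12_heat replicate 1, 1 without cr12_heat replicate 2, 15 without cr2_heat replicate 1 and 12 without cr2_heat replicate 2. With both lines as 1 group, edgeR called 0 genes (2781 at an unadjusted p under 0.05, smallest adjusted p 0.052).

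Heat shock factors differed between the heat-treated htg3 lines. HSFA4d stood at 39.9 ± 1.11 CPM in cr12 and 13.9 ± 0.797 CPM in cr2 (n = 2 each, 1.52 ± 0.25, adjusted p = 0.0067), and HSFB2a at 238 ± 43.8 and 111 ± 14.9 CPM (1.10 ± 0.22, adjusted p = 0.014). HSFA2c (0.71 ± 0.16), HSFB1 (0.70 ± 0.15), HSFA4b (0.65 ± 0.14) and HSFA2e (0.49 ± 0.09) were also higher in cr12. As a list the factors stood higher in cr12 (1.1e-07, adjusted p = 0.036 with an estimated correlation), with a median of 0.49, 6 of 25 called and 8 adjusted over the list alone. With all libraries, 12 factors had an unadjusted p under 0.05, and DESeq2 called 7 and voom 8. The edgeR count was 0 without cr12_heat replicate 2, 1 without cr2_heat replicate 1 and 0 without cr2_heat replicate 2, while the median stayed between 0.48 and 0.62 in every setting. HSFA4d had 1.53 (0.063) without cr12_heat replicate 2 and 1.49 (0.067) without cr2_heat replicate 2. The adjusted p of the other called factors was 0.13 to 0.23 without cr12_heat replicate 2, 0.057 to 0.095 without cr2_heat replicate 1 and 0.063 to 0.18 without cr2_heat replicate 2.

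Against WT after heat, cr2 had 6 of 25 heat shock factors lower (HSFA2c, HSFA2e, HSFA4b, HSFA4d, HSFB1 and HSFC2b), with log2 differences of -0.43 to -1.10. The list had an adjusted p of 0.00025 (adjusted p = 0.11 with an estimated correlation) and 7 lower adjusted over the list alone. HSFB1 (-0.74 ± 0.14, adjusted p = 0.014) lost its call without cr2_heat replicate 2 (-0.67, 0.14). HSFA4d, HSFA2e and HSFA4b lost theirs without cr2_heat replicate 1 (-1.19, 0.061, then -0.43, 0.063, then -0.69, 0.056) or cr2_heat replicate 2 (-1.08, 0.16, then -0.49, 0.087, then -0.61, 0.16). The calls of HSFC2b (lost in 13 of 22 settings, adjusted p up to 0.29) and HSFA2c (lost in 9 of 22, up to 0.22) are not relied on. In cr12 against WT after heat edgeR called 0 of 25 factors (3 at an unadjusted p under 0.05, DESeq2 1, voom 2, list 0.084).

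**Figure D4:**
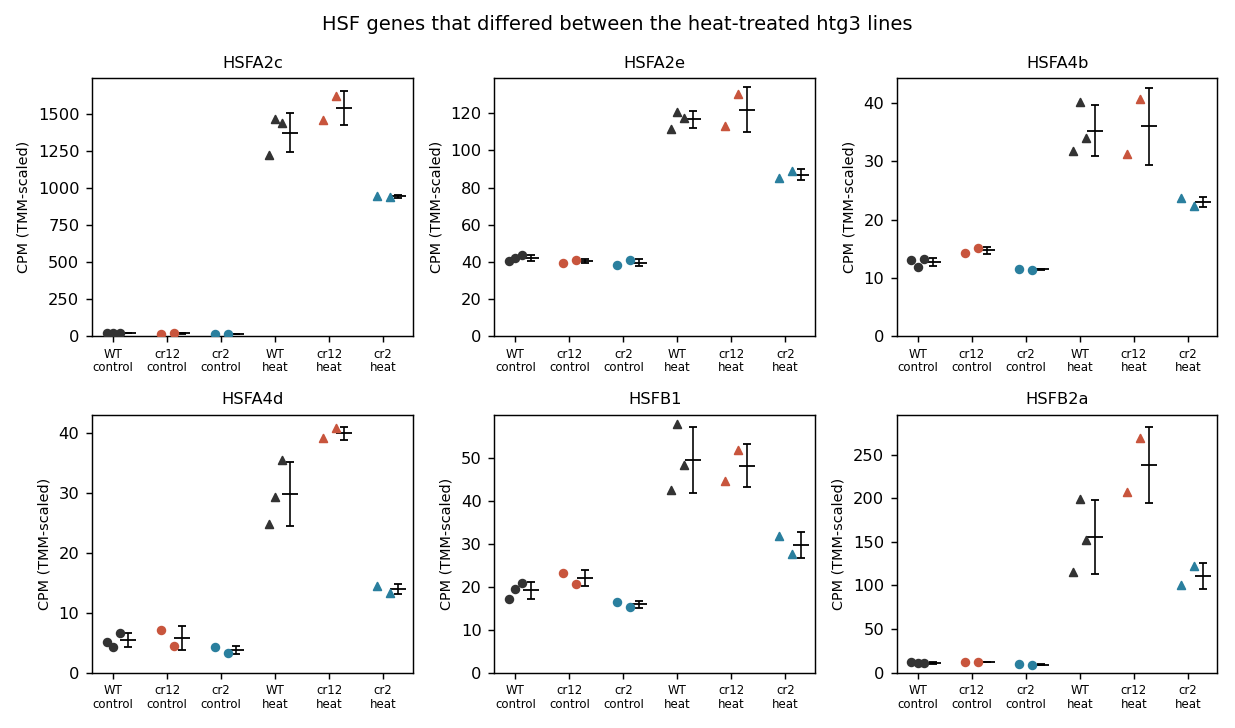
Expression (CPM on TMM-scaled library sizes) of the 6 heat shock factor genes called between the heat-treated lines, with points for libraries (circles untreated, triangles heat-treated) and a bar of mean ± SD beside each group. Heat-treated cr2 lies below heat-treated cr12 in all 6, for HSFA4d at 13.9 against 39.9 CPM.

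Photosynthesis genes were lower in heat-treated cr12 than in heat-treated cr2. The small Rubisco subunit gene LOC_Os12g19470 stood at 259 ± 92.8 against 932 ± 225 CPM (-1.85 ± 0.31, adjusted p = 0.0073), and the antenna gene LOC_Os02g10390 at 739 ± 152 against 1940 ± 83.7 CPM (-1.40 ± 0.25, adjusted p = 0.0093). Without cr12_heat replicate 2 they had -1.48 (0.1) and -1.16 (0.14), and without cr2_heat replicate 2 -1.55 (0.072) and -1.32 (0.076). Light harvesting was lower as a list (3.3e-10, adjusted p = 0.21 with an estimated correlation), with 6 of 13 lower and 11 adjusted over the list alone. So was the photosynthetic apparatus (4e-07, adjusted p = 0.21 with an estimated correlation), with 4 of 7 lower, 7 adjusted over the list alone and 2 under RLE scaling. The senescence regulator NAP was higher in cr12, at 14.3 ± 4.06 against 2.89 ± 0.24 CPM (2.31 ± 0.36, adjusted p = 0.005). SGR, which acts in chlorophyll breakdown, was higher too, at 52.4 ± 8.86 against 18.4 ± 0.646 CPM (1.51 ± 0.26, adjusted p = 0.008). Without cr12_heat replicate 2 NAP and SGR had 2.02 (0.059) and 1.37 (0.082), and without cr2_heat replicate 2 they had 2.25 (0.058) and 1.5 (0.075). In all, 627 genes were higher and 993 lower in heat-treated cr12, 1620 together. The count was 87 without cr12_heat replicate 2, 669 without cr2_heat replicate 1 and 334 without cr2_heat replicate 2.

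Without heat, the cold regulator DREB1C was lower in cr12 than in cr2, at 0.0703 ± 0.0716 against 1.63 ± 0.689 CPM (n = 2 each, -4.52 ± 0.59, adjusted p = 0.0048). This call was lost in 2 of 22 settings (voom and a fit of only the groups compared) and ranged from 6.8e-13 to 0.11 over 8 alternatives. The HSP70 gene LOC_Os05g38530 was higher in cr12, at 37.2 ± 13.5 against 14.7 ± 5.76 CPM (1.34 ± 0.28, adjusted p = 0.025), but not called without cr12_control replicate 2 (0.90, 0.15) or cr2_control replicate 2 (0.95, 0.24), with 2.7e-05 to 0.2 over 8 alternatives. Light harvesting stood lower as a list (3.2e-06, adjusted p = 0.59 with an estimated correlation), with 10 of 13 genes lower adjusted over the list alone and 0 called by edgeR over all genes (10 at an unadjusted p under 0.05, DESeq2 8, voom 0). The antenna gene LOC_Os03g39610 stood at 9590 CPM in cr2_control replicate 2 against 5950 in replicate 1, and at 5280 to 5920 in WT. The list median, -0.74, was -0.36 without cr2_control replicate 2 and -1.09 without cr2_control replicate 1. For cr2 against WT the median, 0.40 (0.0073, adjusted p = 0.71 with an estimated correlation), was 0.01 without replicate 2 and 0.69 without replicate 1. In all, 449 genes were higher and 645 lower in untreated cr12, 1094 together. The count was 124 without cr12_control replicate 1, 327 without cr12_control replicate 2, 1746 without cr2_control replicate 1 and 64 without cr2_control replicate 2. Across both treatments 129 genes were higher and 262 lower in cr12, where independent lists give 9.77 and 22.2.

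In cr12 against WT after heat, MCM7 was higher (1.91 ± 0.30, adjusted p = 0.0085), as was AOS1 (0.89 ± 0.15, adjusted p = 0.0097). Without cr12_heat replicate 2 they had 1.72 (0.078) and 0.79 (0.11), and over 8 alternatives AOS1 ranged from 1.5e-05 to 0.091. JAZ genes stood higher as a list in cr12 (4.1e-05, adjusted p = 0.35 with an estimated correlation), with a median of 0.82, 3 of 13 called and 6 adjusted over the list alone, not independent evidence. In cr2 that list gave no call (0.053, median 0.20, 1 of 13 called, also adjusted over the list alone). It stood higher in cr12 than in cr2 (0.035, adjusted p = 0.44 with an estimated correlation, median 0.24), with 0 of 13 called by edgeR (3 at an unadjusted p under 0.05, DESeq2 2, voom 0), but not without cr12_heat replicate 2 (0.18, 0.39) or cr2_heat replicate 2 (0.29, 0.08). In cr2 after heat, NAP was lower, at 2.89 ± 0.24 against 10 ± 1.11 CPM (-1.79 ± 0.34, adjusted p = 0.012), and MCM2 higher (1.74 ± 0.30, adjusted p = 0.0096). Without cr2_heat replicate 2 they had -1.74 (0.12) and 1.5 (0.09), and over 8 alternatives MCM2 ranged from 3.5e-06 to 0.065. In cr2 without heat, DREB1C was higher, at 1.63 ± 0.689 against 0.212 ± 0.0914 CPM (2.94 ± 0.43, adjusted p = 0.0033, from 1.6e-10 to 0.062 over 8 alternatives). LOC_Os05g38530 was lower there, at 14.7 ± 5.76 against 39.4 ± 2.47 CPM (-1.43 ± 0.26, adjusted p = 0.0095), but not called without cr2_control replicate 2 (-1.05, 0.11), with 3e-07 to 0.093 over 8 alternatives.

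Without heat cr12 differed from WT in 433 genes, 206 of them higher, and cr2 in 1582, 993 of them higher. After heat cr12 differed in 1594 genes, 666 of them higher, and cr2 in 2252, 1197 of them higher. The untreated cr12 count was 154, 230 and 192 without WT_control replicates 1, 2 and 3, and 179 and 128 without cr12_control replicates 1 and 2. The untreated cr2 count was 889, 924 and 945 without WT_control replicates 1, 2 and 3, and 280 without cr2_control replicate 2. After heat the cr12 count was 475 without WT_heat replicate 1 and 861 and 142 without cr12_heat replicates 1 and 2. The cr2 count was 1275 and 1189 without WT_heat replicates 1 and 2, and 1382 and 142 without cr2_heat replicates 1 and 2.

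Both lines were compared with the same WT libraries, which alone makes their differences alike. Without heat cr12 and cr2 shared 109 higher and 67 lower genes against WT, where independent lists give 7.1 and 4.64 and 5 simulations without an effect give 0 and 0. The correlation across genes was 0.376 (0.385 simulated) and the covariance 0.566 (0.273 simulated). After heat they shared 309 higher and 226 lower genes, where independent lists give 27.7 and 34 and the simulations 0 and 0. The correlation was then 0.456 (0.397 simulated) and the covariance 0.748 (0.283 simulated). Without any effect hardly a gene can be called in either line, so 0 shared genes follow from the setting of the simulations. They do not tell how much overlap the shared WT libraries give between lists of called genes, and this stays open.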

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

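The tests of a common origin of the lines and both tests of the difference between the lines were chosen after those results were seen, and so were the shuffling within treatments (in place of a first unrestricted one), the correlations within treatments and within groups, and the comparison of shared genes within those with a count.

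The heat response differed between groups in 33 genes, a difference tested by the interaction. Splits of the libraries say nothing here, because with both lines as 1 group the real split calls 0 genes, so that all 50 of 50 splits reach it (highest other 1). As values, LOC_Os09g28210 had a difference of responses of 1.85, LOC_Os04g49757 of 1.76, LOC_Os12g07970 of -2.08 and LOC_Os03g04530 of -3.53. As lists, these differed in the same test: jasmonate synthesis and signalling (adjusted p = 0.014), ER folding (0.032) and dividing cells (0.014), and none does with an estimated correlation (0.72, 0.72 and 0.95). Each also lost its call without one of several libraries (adjusted p up to 0.092, 0.12 and 0.077). For the heat response in WT the 10 splits, of which the real one is 1, are too few for a share under 0.05 (14177 real, 0 the highest other). For the heat response in the htg3 lines, no other of 35 splits reached the real value (13532 real, 52 the highest other, in the split by line). All splits were fitted to only the libraries compared, with both lines as 1 group, so that variation between the lines counts as spread. Their real values thus differ from the main fit, which called 885 genes for htg3 against WT without heat and 2077 after heat. For htg3 against WT, no other of 35 splits reached the real value without heat (88 real, 3 the highest other) or after heat (269 real, 1 the highest other). Libraries of a line are not independent draws of htg3 plants, so this speaks for these libraries and leaves chance between 2 lines open.

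Between the lines, which were meant to carry mutations of the same gene, 1094 genes differ without heat and 1620 after heat. Were a single untreated library the cause, leaving it out and no other would bring down the 1094 calls, but they fell to 64 without cr2_control replicate 2, 124 without cr12_control replicate 1 and 327 without cr12_control replicate 2, and stood at 1746 without cr2_control replicate 1, so this stays open, also because fewer libraries call fewer genes. After heat the 1620 calls fell to 87 without cr12_heat replicate 2, 669 without cr2_heat replicate 1 and 334 without cr2_heat replicate 2. A different time of harvest could also part the lines, and of 9 clock genes edgeR called 0 in both conditions (0 without heat, with 4 at an unadjusted p under 0.05, and 2 after heat, with 3). DESeq2 called 3 and 3, 1 of them in both, and voom 1 and 3, 0 in both, so this stays open, and no biological explanation was tested.

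Dividing-cell markers stood higher in heat-treated htg3 lines than in heat-treated WT. Scaling does not account for it, as the lowest median with other factors was 1.60. Nor does any 1 library alone, with medians from 1.34 (without WT_heat replicate 1) to 2.33 (without WT_heat replicate 3). Low values in WT_heat replicates 1 and 2 together are not covered by this. Their cyclin and MCM markers deviated from the treatment mean by -1.63 and -1.31, and by -1.1 and -1.26. WT_heat replicate 3 had 0.01 and -0.13, close to cr12_heat replicate 2 at 0.08 and 0.21. More young tissue in some samples would move cyclin and MCM markers together, and the deviations of both marker sets from the treatment mean correlated at 0.794 over 14 libraries (permutation p = 0.003, 0.0058 adjusted over 4 relations), at 0.297 over the untreated ones (exact p = 0.51, rho 0.464) and at 0.984 over the heat-treated ones (exact p = 2e-04, 8e-04 adjusted), but these hold the difference between genotypes itself. Their deviations from the group mean correlated at 0.822 (exact p = 0.042 over 576 shuffles within groups, 0.056 adjusted). Joint movement was thus not shown among untreated libraries, and markers of a shared programme may move together without any difference in tissue, so this stays open.

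Genes with at most 12 counts in each WT treatment and at least 1 CPM in both groups of a line numbered 10 in cr12 and 13 in cr2, of which 3 were shared, LOC_Os07g15340, LOC_Os01g36064 and LOC_Os01g62740. The cut leaves out genes with somewhat more counts in WT but higher levels in the lines. LOC_Os03g02470 had 0.0742 and 0.22 CPM in untreated and heat-treated WT, against 61.9 and 58.4 in cr12 and 44.5 and 40 in cr2. LOC_Os03g43100 had 0 and 0.0864 CPM in WT, against 11.4 and 13.7 in cr12 and 11 and 11.1 in cr2. A chromosome segment from another background would set such genes side by side, and 0 of the 3 have another within 10 loci (exact 95% upper bound of 0.708), which cannot tell. Separate changes that strike silent genes with equal chance would share 0.00485 genes among the 26813 silent in WT, or 0.0198 among the 6578 of these with a count in some library, and the 3 shared argue against them, though not against separate changes at loci prone to change. Loss of HTG3 and a common origin of the transgenic lines could both give shared genes, and with 3 genes and no library that separates the explanations the test cannot tell. In the other direction, LOC_Os02g43050 stood at 9.12 and 9.25 CPM in untreated and heat-treated WT and had 0 counts in the htg3 lines.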

How the results depend on the processing

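Counts divided by 4 and the fit without 2 libraries were chosen after seeing the data. No paired analysis was possible because the labels pair no libraries. The 203 named calls followed here are mostly of the heat responses, and loci without a symbol are not among them. For htg3 against WT, listed genes gave 1 call without heat and 15 after heat, most of which were lost in at least 1 setting. No named gene reversed its direction under any alternative, and 193 to 202 of 203 named calls stayed with a library left out, 191 in fits of only the groups compared and 192 without 2 libraries. Counts for the heat responses moved little with a library left out, 13141 to 14522 in WT and 14604 to 16366 in the htg3 lines, and the 2-fold minimum left 7527 and 7941. The other counts moved, and the cause was not tested beyond fewer libraries or a stricter minimum. For the interaction (33) they were 12 with RLE factors, 126 without a filter, 1247 with DESeq2, 10 with voom, 0 with both lines as 1 group, 50 with counts divided by 4, and 0 to 84 with a library left out. For htg3 against WT without heat (885) they were 2239 with DESeq2, 386 with the 2-fold minimum (77.7% higher against 56.7%), 379 with both lines as 1 group and 331 to 1049 with a library left out. After heat (2077) they were 4388, 635, 621 and 718 to 2498, with 758 in a fit of only the groups compared and 1004 without 2 libraries. For cr12 against WT without heat (433) DESeq2 gave 1726, voom 695, the 2-fold minimum 228, the fit without 2 libraries 658, and a library left out 128 to 582. For cr2 without heat (1582) DESeq2 gave 3198, the 2-fold minimum 848, the fit without 2 libraries 355, and a library left out 280 to 1851. For cr12 after heat (1594) DESeq2 gave 3551, the 2-fold minimum 530, only the groups compared 95, and a library left out 142 to 2039. For cr2 after heat (2252) they were 4451, 861, 292 and 142 to 2507, with 1325 without 2 libraries. For cr12 against cr2 without heat (1094) they were 3152, 539, 22 and 64 to 1746, with 67 without 2 libraries. After heat (1620) they were 2903, 668, 628 and 87 to 1757. Lists called over the main comparisons fell from 31 to 7 with an estimated correlation. Depth limits little for well-covered genes, as replicate spread was 11.4 to 39.2 times that of sampling over genes above a minimum count. For genes near the floor this ratio does not tell how far depth limits the results.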

Other observations

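The tests in this closing part are those weighed among the results above, and no further hypothesis was tested. Beside the groups above, BiP1 stood at 182 ± 5.94 CPM in untreated cr12 and 202 ± 30 CPM in untreated cr2 against 142 ± 19.9 CPM in untreated WT (log2 difference 0.43, adjusted p = 0.087 with edgeR), which is not a call. The light harvesting list stood higher in heat-treated cr2 than in heat-treated WT (adjusted p = 0.0055, and 0.53 with an estimated correlation, 13 of 13 positive, 0 called by edgeR, 3 at an unadjusted p under 0.05, DESeq2 0, voom 0, and not called without WT_heat replicate 3, at 0.095) and lower in heat-treated cr12 than in heat-treated WT (1.8e-05, and 0.35 with an estimated correlation).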
